A study of Homo sapiens with 7 samples.

How the data were processed

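The series profiled DNA binding of ATF4 and MYC by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in DLD-1, an established human colon adenocarcinoma cell line that had been infected with a retrovirus expressing MycER, a MYC protein fused to an estrogen receptor domain that becomes active when 4-hydroxytamoxifen is added. Per the labels, ATF4 was profiled in 2 control samples and in 2 samples taken after 8 hr of MYC activation, MYC was profiled in 2 samples after 8 hr of activation, and 1 sample is an IgG immunoprecipitation. The inducer was used at 500 nM, and the labels give no concentration for the control samples. No group had the inducer without MycER, so an effect of the inducer itself cannot be told apart from MYC activation. Groups and replicate numbers were taken from the sample titles. The labels do not say whether replicates came from separate cultures, so p-values that compare libraries measure only the spread between these samples, which may be technical. MYC in control cells was not analysed here.

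Each of the 6 ATF4 and MYC samples had 1 peak list, called per library and not on pooled reads. No peak list of the IgG sample was used, and it entered only through the background columns of the other lists, if it was their background library, which the file headers do not name. Bowtie 0.12.9, HOMER and the hg38 build are named per the submitters' processing notes, without their settings. The columns are those of HOMER's peak finder per the file headers. The main value is the normalized tag count, a signal that the authors scaled to 10 M tags per library. The deposited lists also give a peak score, a focus ratio that is a fraction between 0 and 1, the fold over the background library and over the surroundings, and the p-value of each comparison. The total tags per peak are a whole-number count in the replicate 1 lists, per the file headers, and a signal scaled down to the background library in the replicate 2 lists. The score, the fold and the p-value of a peak are the authors' own values and were used only to describe, rank or filter peaks within a list. Every deposited peak had a p-value over background under 0.05 and a fold over its surroundings of at least 4.

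Library depth was read from the steps between low normalized tag counts, which were constant within each list. The replicate 1 libraries held 22.4 M tags (ATF4, control), 24.95 M (ATF4, activated) and 21.04 M (MYC), and the replicate 2 libraries held 50.3, 49.75 and 50.1 M. The same normalized tag count therefore rests on more reads in replicate 2 than in replicate 1. The background library, read from the replicate 2 lists, held about 43.3 M tags. Because depth follows the replicate number, values are given per replicate number beside the pooled values of each comparison, for gene lists as the number of members with a peak in 1 library alone, with adjustment over the 88 tests of each replicate number. Exact (Clopper-Pearson) 95% binomial intervals are given for shares and cover counting error only.

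Peaks that overlapped by at least 1 bp were merged into regions, separately for ATF4 and MYC. A region counted as reproducible in a condition when both of its libraries had a peak there. Activated-only regions had a peak in both activated and in neither control library, and control-only regions the reverse. Numbers of peaks were compared by a two-sided exact permutation test over libraries. ATF4 signal was compared at the regions with a peak in all 4 ATF4 libraries, with the strongest peak per region and library, by limma with a trend on log2(normalized tag count + 1), and p-values were adjusted by the Benjamini-Hochberg method over regions with a threshold of 0.05. The plan had been a count test if all lists held whole counts, which the replicate 2 lists do not. Fold changes are on the log2(value + 1) scale, which understates the change of weak regions. Such a test covers only sites with a called peak in every library.

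Overlap of ATF4 with MYC regions (at least 1 bp) was compared with 1000 placements of the same regions at random on their chromosome, with 1000 placements that moved regions at gene ends to random gene ends, and with 1000 shifts of 5 to 50 kb, by one-sided permutation tests whose smallest possible p is 0.001. The shifts were added after the data were examined. Other region and gene comparisons used Fisher's exact test, two-sided. Regions and genes are not replicates, and these tests describe the lists.

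The gene annotation was that of GRCh38.p14, which gives the span of each gene without strand or transcription start. The planned promoter window of 1000 bp around a transcription start was therefore replaced by 1000 bp around either end of an annotated gene span, called a gene end here. Among 593 genes with an annotated divergent transcript, which lies beyond the end where transcription starts, MYC regions lay at that end in 72. They lay at the other end in 3. Reproducible ATF4 regions of activated cells lay at neither end of these genes, so this check does not cover ATF4. An added alternative counted regions inside a gene or within 1000 bp of it, and compared each list with 10000 random lists matched on gene length (smallest possible p 1e-04). The annotation used does not separate exons from introns. A region inside a gene is therefore reported without that distinction, and may lie at a transcription start within the span. No genome sequence was used, and the planned motif counts were not run.

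Gene list enrichment was tested by a one-sided Fisher's exact test over 19974 protein-coding genes of chromosomes 1 to 22 and X, with Benjamini-Hochberg adjustment over 88 tests (22 lists, and ATF4 control, ATF4 activated, MYC and genes with both factors). The lists, with 549 members in all, were fixed before the data were examined and covered amino acid synthesis, one-carbon metabolism, amino acid transporters, cytosolic and mitochondrial aminoacyl-tRNA synthetases, integrated stress response regulators, unfolded protein response chaperones, autophagy, translation initiation and elongation factors, translation repression and mTORC1, cytosolic ribosomal proteins, ribosome biogenesis, classical MYC targets, proteasome subunits, glycolysis, cholesterol synthesis, NRF2 targets, circadian and CLEAR E-box genes, colon epithelium, and markers of blood cells, fibroblasts and neurons. The rule for named genes was also fixed before the data were examined. It takes the first 10 genes per set of regions at gene ends, ranked by the mean percentile of the normalized tag count in the replicate lists, up to 4 members per list for ATF4 and for MYC, up to 10 regions past the threshold of the tag test by fold change, and ATF4, MYC, EIF4EBP1, ASNS and DDIT3 in any case. Genes outside this rule are marked in the text as chosen after their values were seen.

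Alternatives set before the data were examined were the upper 50% of each list by tags, lists shortened to equal length, other definitions of overlap, gene-end windows of 200 and 5000 bp, another background of genes, a replicate block, median centring, a pseudocount of 5, a minimum mean of 20 tags and leaving out each library in turn. Added later were a fold over background of at least 4, leaving out chromosomes 2 and 8, ATF4 peaks only from the higher of the lowest tag counts of the control and activated lists of a replicate number (a common lowest tag count), and the count of regions inside genes. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1. The steps were tested on simulated data. For the tag test, 25 simulated data sets of 105 regions with 30 changed gave 95.2% of 2-fold and 100% of 3-fold changes, with 0.84 and 1.04 false calls per data set, and 25 data sets without change gave 0.08 calls each. These held no factor shared by all regions of a library. With such factors at a log2 SD of 0.125, data sets without change gave 0.04 calls each. Larger shifts of a whole library were not simulated for this test, so it does not show that calls are safe from them. In 25 simulations the planted gene list was found each time with 0 false calls.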

Results

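The data are 6 peak lists from DLD-1 MycER colon cancer cells, 2 libraries each of ATF4 in control cells, ATF4 after 8 hr of MYC activation and MYC after 8 hr of activation. DLD-1 is an established line of colon adenocarcinoma cells, MycER is a MYC protein that 4-hydroxytamoxifen switches on, and ChIP-seq sequences the DNA bound by an immunoprecipitated protein. The replicate 1 libraries held 22.4, 24.95 and 21.04 M tags in that order and the replicate 2 libraries 50.3, 49.75 and 50.1 M, and 1 IgG sample entered only as possible background. ATF4 is a transcription factor of the integrated stress response that drives genes of amino acid supply, and MYC is a growth-promoting transcription factor. MYC was profiled only after activation, so MYC activity in control cells was not analysed here. The comparisons are ATF4 binding with and without activation of MycER, and the sites and genes that the 2 factors share. Coordinates are those of hg38, and signal is the authors' normalized tag count per 10 M tags, called tags here.

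Strong reproducible ATF4 regions in activated cells lay at genes of the stress response and amino acid metabolism and at others. Examples of the latter, chosen after their values were seen, lay inside TBC1D16, a GTPase regulator (33.7 and 34.4 tags in activated replicates 1 and 2), and 9275 bp from TCP11L2 (28.1 and 28.3). The strongest at a gene end (chromosome 19, 48755347 to 48755568) lay 67 bp from FGF21, a stress-induced hormone, and 99 bp from FUT1, with 42.5 and 33.6 tags in activated replicates 1 and 2 and 22.3 and 14.5 in control replicates 1 and 2. CHAC1, a glutathione-degrading enzyme, had a region 185 bp from its end (chromosome 15, 40953180 to 40953393) with 28.5 and 24.3 tags after activation and 14.3 and 10.3 in control. PCK2, mitochondrial phosphoenolpyruvate carboxykinase, had 23.7 and 18.3 against 12.5 and 11.5 tags. Strong MYC regions at gene ends belonged to genes of several kinds. NME1, a nucleoside diphosphate kinase, had 27.1 and 43.3 tags 25 bp from its end (chromosome 17, 51153419 to 51153650), and NOLC1 and NAT10, nucleolar proteins, had 25.7 and 40.3 and 26.6 and 39.7. HMGA2, a chromatin protein, had 27.1 and 28.7, ATP5MK of the ATP synthase, which shares its region with PDCD11, 26.6 and 31.5, and DIPK1A, which shares its region with RPL5, 22.8 and 35.9.

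ATF4 lists held 916 and 1579 peaks in control and 1270 and 2231 peaks in activated replicates 1 and 2, and MYC lists held 8636 and 22532. Of the shorter list, the replicates shared 151 regions in ATF4 control (16.5%, interval 14.1 to 19.05%), 352 in ATF4 activated (27.7%, 25.3 to 30.3%) and 6313 in MYC (73.1%, 72.2 to 74.0%). The median fold over background was 4.64, 3.44, 5.21 and 4.57 in the ATF4 lists, in the order above, and 9.26 and 7.78 in the MYC lists. In the ATF4 lists 12.3%, 11.8%, 10.3% and 5.56% of peaks had a fold over background under 2. The activated libraries had more peaks than the control libraries in both replicate numbers (1.39 and 1.41 times). The lowest tag count listed was 4.46 in control and 3.21 in activated replicate 1, and 2.98 and 2.81 in replicate 2. With peaks from the higher of these up, an alternative chosen after seeing the data, the ratios were 1.05 and 1.41. The means of 1750.5 ± 679.5 and 1247.5 ± 468.8 peaks (SD, n = 2) could not be told apart by the two-sided exact permutation test (p = 0.67), which cannot give a p below 0.33 with 2 against 2 libraries.

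The question of whether MYC activation changes where ATF4 is found was addressed first by the presence of peaks. Among the genes with an activated-only ATF4 region at their end were MARS1, which shares its region with ARHGAP9 (7.22 and 8.04 tags in activated replicates 1 and 2), and NARS1 (4.81 and 6.83), both aminoacyl-tRNA synthetases that load amino acids onto tRNA. Amino acid supply genes among them were PSAT1 of serine synthesis (6.41 and 6.63) and SLC38A1, a glutamine transporter (6.01 and 6.03). Others were DUSP28, a phosphatase (9.62 and 8.84), RACK1, a ribosomal scaffold (7.22 and 6.23), TAF15, an RNA-binding protein (7.22 and 6.03), and the pair TXNDC12 and BTF3L4, which share a region (6.41 and 8.04). Genes of the fixed lists in this state were GPT2, alanine aminotransferase (4.41 and 7.23), and MTHFD2 of the mitochondrial folate cycle (4.41 and 9.44), both under the lowest tag count of control replicate 1 (4.46), where such a peak would not have been listed. The only gene with a control-only region at its end was STX6, a syntaxin (5.36 and 4.37 tags in control replicates 1 and 2). DDIT3, which encodes the stress factor CHOP, had a peak in activated replicate 2 only (5.83 tags), and the ATF4 gene had no ATF4 or MYC region.

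Of 151 control and 352 activated regions, 105 were reproducible in both conditions, which is 69.5% of the control regions. A further 152 regions were activated-only and 17 were control-only. The highest fold over background was under 2 at 18 of the 151 control regions, 2 of the 105 in both conditions and 6 of the 352 activated. Among the strongest control regions was such a region 58917 bp from CWH43, chosen after its values were seen. It had 33.5 and 29.4 tags at folds of 1.69 and 1.3 in control replicates 1 and 2, and no peak in activated replicate 2. Of the activated-only regions, 27 had fewer than the 4.46 tags of the lowest control peak in replicate 1, and with peaks from a common lowest tag count 125 were left. Within replicate 1, 220 regions had a peak in both conditions, 1050 in the activated library only and 696 in the control library only, and within replicate 2 the numbers were 235, 1996 and 1344. Pairing the 4 libraries by replicate number gave 68 regions only in the pair of replicate 1 and 56 only in that of replicate 2, and the remaining pairing gave 15 and 34. The control-only regions had a median highest fold over background of 2.62, against 8.27 for activated-only regions. With peaks of at least 4-fold over background, an alternative chosen after seeing the data, the numbers were 82 in both, 131 activated-only and 1 control-only.

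At the 105 regions with a peak in all 4 ATF4 libraries, ATF4 tags rose at 39 and fell at 0 (limma, adjusted p under 0.05). With a replicate block, an alternative set before the data were examined, 0 passed (smallest limma adjusted p 0.115). Stress response and amino acid genes were among the regions with the largest change. ASNS, asparagine synthetase, rose from 6.08 ± 0.396 to 14.65 ± 0.919 tags (SD, n = 2) at a region inside the gene (chromosome 7, 97872341 to 97872590), a log2 change of 1.14 with a standard error of 0.29 (limma adjusted p = 0.00601). CHAC1 rose from 12.3 ± 2.83 to 26.4 ± 2.97 tags, a log2 change of 1.06 with a standard error of 0.30 (adjusted p = 0.00904), and FGF21 from 18.4 ± 5.52 to 38.05 ± 6.29 tags, a log2 change of 1.03 with a standard error of 0.32 (adjusted p = 0.0114). The largest change was inside TEK, an endothelial receptor kinase (chromosome 9, 27194394 to 27194644), from 6.9 ± 0.919 to 17.55 ± 1.06 tags, a log2 change of 1.24 (adjusted p = 0.00309). The next by size were regions inside FNDC3B (1.11), 15176 bp from CYP2A7 (1.04), 140454 bp from VEGFA (1.03), inside PGPEP1 (1.00), inside ATXN1 (0.98) and inside EEIG1 (0.97). In all 39 regions that passed, both activated libraries had more tags than both control libraries.

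By gene list, 3 of the 4 stress response regulators with a common region rose (CHAC1, FGF21 and VLDLR, a lipoprotein receptor with a log2 change of 0.89), as did 3 when adjusted over the list alone. EIF4EBP1, the translation repressor 4E-BP1, did not pass, with 10.4 ± 0.424 tags in control and 15.85 ± 5.44 after activation (adjusted p = 0.125). Of 4 amino acid transporters 1 rose, SLC1A5, a glutamine carrier (7.695 ± 2.04 to 13.95 ± 3.89 tags), and 4 passed when adjusted over the list alone, with log2 changes of 0.78 for SLC1A5, 0.70 for SLC43A1, 0.63 for SLC7A5 and 0.58 for SLC7A11, the cystine carrier. Their median of 0.67 was near that of all 105 common regions (0.54), of which 57 were higher at an unadjusted limma p under 0.05. Passing over such a short list therefore sets them little apart. Of 2 regions at amino acid synthesis genes, ASNS rose and SHMT2, serine hydroxymethyltransferase, did not pass (log2 change 0.34, adjusted p = 0.302), and the same 1 region passed when adjusted over the list alone. SHMT2 was also the only common region of the one-carbon list, XBP1 that of the unfolded protein response list (log2 change 0.39) and EIF4EBP1 that of the mTORC1 list, with 0 passing by either adjustment. SLC7A11 was the only region of the NRF2 list, with 0 passing over all regions and 1 when adjusted over the list alone, which for 1 region is no adjustment. SLC1A5, SLC43A1, SLC7A5 and XBP1 have their regions inside the gene and were chosen after their values were seen.

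**Figure D1:**
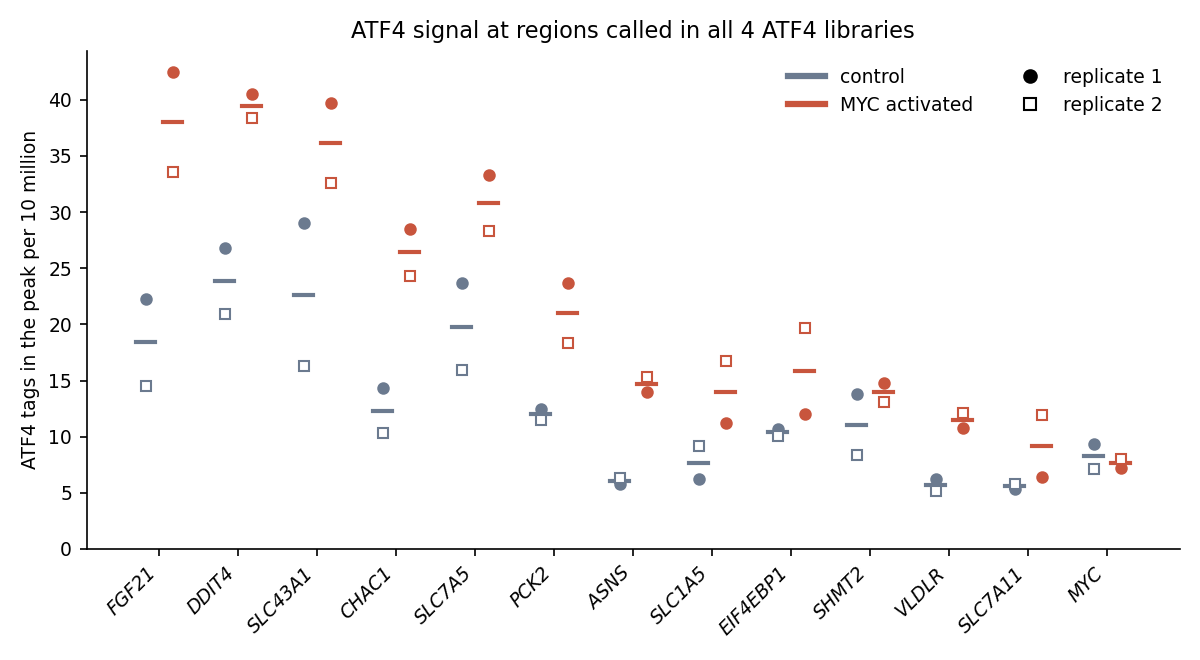
ATF4 signal (normalized tags per 10 M, vertical axis) at regions of 13 genes called in all 4 ATF4 libraries, with 1 point per library, circles for replicate 1, squares for replicate 2, and a bar at the mean of each condition. Tags at CHAC1 were 14.3 and 10.3 in control and 28.5 and 24.3 after activation, and the region inside MYC had 9.38 and 7.16 against 7.22 and 8.04.

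The median log2 change over the 105 regions was 0.54, with a median of 0.37 in replicate 1 and 0.74 in replicate 2, and tags were higher after activation in both replicate numbers at 82 regions and lower in both at 5. The calls depend on the scaling to library depth, since centring each library on its median over the regions gave 0 higher and 9 lower, with 2 and 18 at an unadjusted p under 0.05, against 39 and 0 with 57 and 0. The centring moved the median change from 0.54 to -0.11. Relative to the typical common region, then, no region passed as higher. Leaving out control replicate 1, control replicate 2, activated replicate 1 or activated replicate 2 left 0 regions past the threshold (smallest limma adjusted p 0.0872, 0.164, 0.0623 and 0.141), with 47, 24, 40 and 25 regions higher at an unadjusted p under 0.05, where the lone sample is assumed to vary like the other group.

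**Figure D2:**
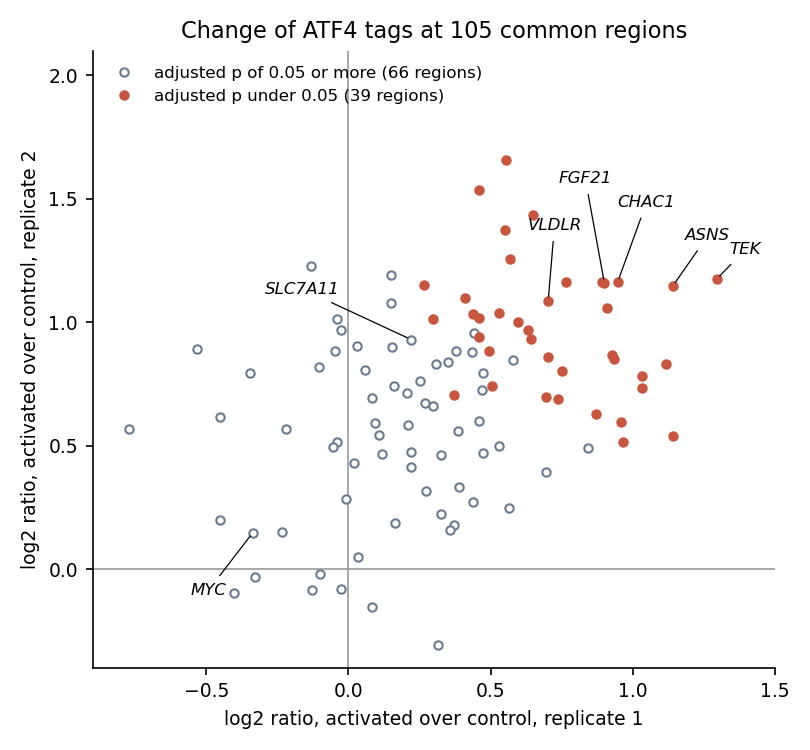
Log2 ratio of ATF4 tags, activated over control, in replicate 1 (horizontal axis) and replicate 2 (vertical axis), with 1 point for each of the 105 common regions, filled where the limma adjusted p was under 0.05 (39 regions). Ratios were above 0 in replicate 1 at 84 regions and in replicate 2 at 98, on the scaling to 10 M tags, which median centring over the regions takes to 0 higher and 9 lower calls.

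Whether ATF4 and MYC occupy the same sites was then compared in activated cells. The strongest shared regions lay inside SLC43A1, a carrier of large neutral amino acids (39.7 and 32.6 ATF4 tags in activated replicates 1 and 2), TBC1D16 (33.7 and 34.4) and SLC7A5, another such carrier (33.3 and 28.3). Further strong ones lay 260199 bp from KLF4 (14.4 and 16.9), 7738 bp from NRSN2 (15.2 and 15.7), inside ATXN1 (16 and 13.9), and inside OXR1 (18.4 and 11.5). These regions away from gene ends were chosen after their values were seen. At EIF4EBP1 (12 and 19.7) the ATF4 region (chromosome 8, 38031409 to 38031639) overlapped a MYC region with 11.9 and 23.9 tags. STK40, a kinase (17.2 and 19.1), and TBL1X, a corepressor subunit (5.61 and 7.84), also had shared regions at their ends. In all, 65 of 352 reproducible activated ATF4 regions overlapped a reproducible MYC region (18.5%, interval 14.6 to 22.9%), and these took up 65 of 6313 MYC regions (1.03%). Random placements on the same chromosome gave a mean of 0.352 regions, placements that kept gene ends 0.787 and shifts of 5 to 50 kb 1.03, each with a one-sided permutation p of 0.001, the smallest that 1000 placements can give. None of these placements was matched on DNA that is accessible in these cells. The test therefore cannot tell a link between the 2 factors from separate binding to the same accessible sites. Control ATF4 regions exceeded their shifts as well (27 regions against a mean of 0.447). Within replicate numbers, 9.92% of activated ATF4 peaks overlapped a MYC peak in replicate 1 and 12.7% in replicate 2. The share moved with the library left out, to 42.6% without MYC replicate 1, 19.9% without MYC replicate 2, 4.48% without ATF4 activated replicate 1 and 5.67% without ATF4 activated replicate 2. In each case the remaining library alone defined its condition, so peaks that were not reproducible were counted too.

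Regions found only after activation did not lie on MYC regions more often than those found in both conditions. MARS1, NARS1, SLC38A1 and TXNDC12 were activated-only and overlapped a MYC region, and EIF4EBP1, SLC7A11, STK40 and TBL1X were found in both conditions and did so too. The share was 23 of 152 (15.1%) for activated-only regions, 26 of 105 (24.8%) for regions in both and 0 of 17 for control-only regions. The first pair had an odds ratio of 0.54 (two-sided Fisher's exact test, p = 0.0748). Of the control ATF4 regions, 27 of 151 (17.9%) overlapped a MYC region, with 9.06% and 7.35% of control peaks in replicates 1 and 2. Without ATF4 activated replicate 1, ATF4 activated replicate 2 or MYC replicate 1 the odds ratio was 0.0889, 0.132 and 0.459. The library left then defines its condition alone, so peaks that the other replicate lacked were counted too. These lower ratios therefore do not show that activated-only sites avoid MYC regions.

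**Figure D3:**
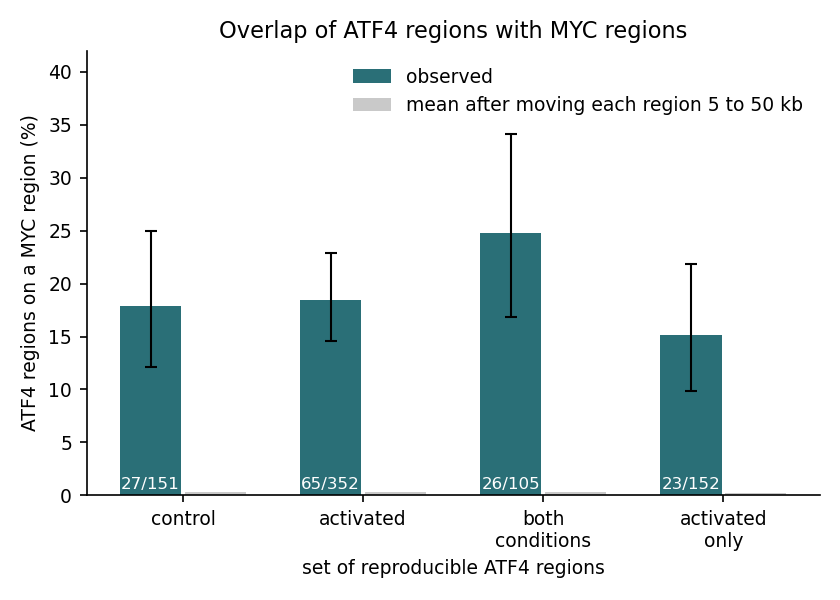
Percent of reproducible ATF4 regions that overlap a reproducible MYC region, by set of ATF4 regions, with exact 95% binomial intervals, beside the mean after 1000 shifts of each region by 5 to 50 kb. The share was 18.5% for activated, 17.9% for control, 24.8% for regions in both conditions and 15.1% for activated-only regions, and shifted regions gave 0.296% for control and 0.291% for activated.

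At the level of genes, 16 had both an ATF4 and a MYC region at an end in activated cells. Amino acid supply and protein synthesis genes among them were SLC7A11, SLC38A1 and SLC38A2, the synthetases MARS1 and NARS1, PSAT1 and RACK1. Stress response genes among them were CHAC1, CEBPB, a transcription factor, and EIF4EBP1. The others were ARHGAP9, BTF3L4, TXNDC12, IRAK1BP1, STK40 and TBL1X. The 16 were 41.0% of 39 genes with an ATF4 region, against 2028 of 19974 genes (10.2%) with a MYC region (odds ratio 6.20, two-sided Fisher's exact p = 4.65e-07). This background of all genes was not matched on accessible DNA either. At CHAC1, PSAT1, RACK1 and SLC38A2 the regions of the 2 factors did not overlap and their centres were 413, 538, 845 and 541 bp apart, and at the other 12 genes they overlapped. The odds ratio was 18.7 without MYC replicate 1, 1.86 without ATF4 activated replicate 1 and 3.29 without ATF4 activated replicate 2. Within replicate numbers it was 3.51 (28 of 89 genes) in replicate 1 and 3.36 (128 of 210) in replicate 2.

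ATF4 regions in activated cells were enriched at 5 of the 22 gene lists, counted within 1000 bp of a gene end. Stress response regulators had 5 of 27 members at an ATF4 region (CHAC1, CEBPB, VLDLR, FGF21 and EIF4EBP1, adjusted p = 3.74e-08), amino acid synthesis 4 of 23 (PHGDH, PSAT1, SHMT2 and GPT2, 1.57e-06) and cytosolic aminoacyl-tRNA synthetases 4 of 24 (IARS1, MARS1, NARS1 and YARS1, 1.61e-06). Amino acid transporters had 3 of 23 (SLC7A11, SLC38A1 and SLC38A2, 9.49e-05) and one-carbon metabolism 2 of 18 (MTHFD2 and SHMT2, 0.00377), all by one-sided Fisher's exact tests against 39 of 19974 genes. In tags, IARS1 had 8.82 and 11.3 and YARS1 6.81 and 9.44 in activated replicates 1 and 2, with 4.77 in control replicate 2 only and 4.91 in control replicate 1 only. PHGDH, the entry enzyme of serine synthesis, had 8.02 and 11.9, with 6.96 in control replicate 2 only. NRF2 targets (1 of 17, SLC7A11, adjusted p = 0.111) and the mTORC1 list (1 of 22, EIF4EBP1, 0.137) did not pass, and the remaining 15 lists, markers of blood cells, fibroblasts and neurons among them, had 0 members. With the peaks of each activated library alone, the members in replicates 1 and 2 were 5 and 9 stress response regulators, 4 and 5 amino acid synthesis genes, 4 and 8 synthetases, 5 and 3 transporters and 2 and 2 one-carbon genes. The last list did not pass in replicate 2 (adjusted p = 0.051 by the exact test), where the mTORC1 list did (4 of 22, adjusted p = 4.39e-04), so that 5 lists passed in each library. Within 200 bp of a gene end only stress response regulators (2 of 27, adjusted p = 0.00171 by the exact test) and synthetases (4 of 24, 5.01e-08) passed, while amino acid synthesis and transporters (1 of 23 each, 0.077) and one-carbon metabolism (0 of 18) did not. Within 5000 bp 8 lists passed, with unfolded protein response chaperones, the mTORC1 list and NRF2 targets added. One-carbon metabolism also did not pass in the upper 50% of each list, with lists of equal length or with peaks from a common lowest tag count, each of which left 4 lists.

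In control cells 1 list passed, the stress response regulators with 4 of 27 (CHAC1, VLDLR, FGF21 and EIF4EBP1, one-sided Fisher's exact test, adjusted p = 4.62e-08), and 0 of 24 synthetases had a region. With each control library alone, 1 list passed in replicate 1 and 4 in replicate 2, where amino acid synthesis (3 of 23), transporters (2 of 23) and synthetases (3 of 24) passed too. The difference between conditions was not tested. The number of lists in control cells was 4 without ATF4 control replicate 1 and 3 without MYC replicate 1, whose list enters the joint adjustment. Genes with both factors were enriched for transporters (3 of 23, adjusted p = 8.14e-06), stress response regulators (3 of 27, 1.19e-05) and cytosolic synthetases (2 of 24, 0.00121), and 5 lists passed without MYC replicate 1. Within 200 bp, stress response regulators had 0 of 27 and NRF2 targets passed (1 of 17, adjusted p = 0.0299 by the exact test). Synthetases with both factors did not pass in the upper 50% of each list or at 4-fold over background. Genes with both factors are a part of the genes with an ATF4 region in activated cells. Those were already enriched for transporters, stress response regulators and synthetases. The tests against all genes therefore do not show that joint binding favours these lists. When regions inside genes were counted too, with length-matched lists, an alternative chosen after seeing the data, one-carbon metabolism no longer passed in activated cells (permutation, adjusted p = 0.0535), and NRF2 targets (0.0235) and the mTORC1 list (0.0083) did. By the same permutation test the number of lists was 3 in control cells, with amino acid synthesis and transporters added, and 6 for both factors, with amino acid synthesis, the mTORC1 list and NRF2 targets added. Each replicate alone gave 3 and 5 lists for both factors.

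MYC regions were enriched at 7 lists, led by the protein synthesis machinery. Cytosolic ribosomal proteins had 51 of 78 genes with a MYC region (65.4%, one-sided Fisher's exact test, adjusted p = 4.56e-30), among them RPL5 (22.8 and 35.9 tags in replicates 1 and 2), RPS18 (17.6 and 24.9), RPL32 (18.5 and 21.4) and RPL9 (16.2 and 22.2). Ribosome biogenesis had 22 of 36 (5.12e-12), with NOLC1, NOP16 (22.8 and 33.7), GNL3 (18.1 and 25.3) and DDX21, an RNA helicase (14.3 and 24.5). Classical MYC targets had 20 of 39 (3.73e-09), among them NME1, ENO1, enolase of glycolysis (12.4 and 23.9), and APEX1, a DNA repair enzyme (11.9 and 18.6). Translation factors had 15 of 40 (3.59e-05), among them EIF4B (18.1 and 28.5), EIF3E (14.7 and 17.2) and EIF4A1 (9.03 and 19.2). The list of cytosolic synthetases had 8 of 24 (0.0116), among them FARSB (13.8 and 29.7) and AIMP2 (15.7 and 21.8), an accessory protein on that list and not itself a synthetase. Glycolysis had 7 of 20 (0.0152), among them LDHB (13.8 and 31.7) and GAPDH (5.70 and 18.0). NRF2 targets had 6 of 17 (0.0276), among them FTL, ferritin light chain (8.08 and 20.2), and OSGIN1 (10.5 and 18.6).

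The other lists did not pass for the MYC regions found in both replicates by the same exact test. Proteasome subunits had 7 of 31 (adjusted p = 0.111), circadian and CLEAR genes and amino acid transporters 5 of 23 each (0.233), mitochondrial synthetases 4 of 17 (0.253), one-carbon metabolism 4 of 18 (0.291), stress response regulators 5 of 27 (0.365), the mTORC1 and cholesterol synthesis lists 4 of 22 each (0.462), amino acid synthesis 4 of 23 (0.503) and colon epithelium 3 of 19 (0.74). Autophagy had 3 of 25, unfolded protein response chaperones 2 of 22 (HSPA5 and HERPUD1), blood cell markers 1 of 16 (CD8A), neuron markers 1 of 14 (RBFOX3) and fibroblast markers 0 of 12, each with an adjusted p of 1. The number of lists that passed for MYC was 11 without MYC replicate 1. With each MYC library alone 7 and 11 lists passed in replicates 1 and 2, with 61 and 75 of 78 ribosomal proteins, 24 and 32 of 36 ribosome biogenesis genes and 13 and 22 of 24 cytosolic synthetases. NRF2 targets did not pass in replicate 1 (adjusted p = 0.0509). Proteasome subunits passed in each MYC library alone by the exact test (9 and 21 of 31, adjusted p = 0.0395 and 2.97e-04). In replicate 2 alone, mitochondrial synthetases (15 of 17, 1.83e-05), amino acid synthesis (15 of 23, 0.00503) and unfolded protein response chaperones (13 of 22, 0.0291) passed as well. When regions inside genes were counted too, with length-matched lists, cytosolic synthetases (10 of 24, permutation, adjusted p = 0.052) and glycolysis (8 of 20, 0.0584) no longer passed for MYC, and amino acid transporters did (13 of 23, 7.00e-04). Within 200 bp of a gene end glycolysis (1 of 20, adjusted p = 1 by the exact test) and NRF2 targets (2 of 17, 0.517) did not pass, and within 5000 bp glycolysis did not (0.0889). With lists of equal length NRF2 targets did not pass. Against only genes with a peak of any library at an end, a background made up mostly by the MYC lists, 3 lists passed, ribosomal proteins, ribosome biogenesis and classical MYC targets.

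**Figure D4:**
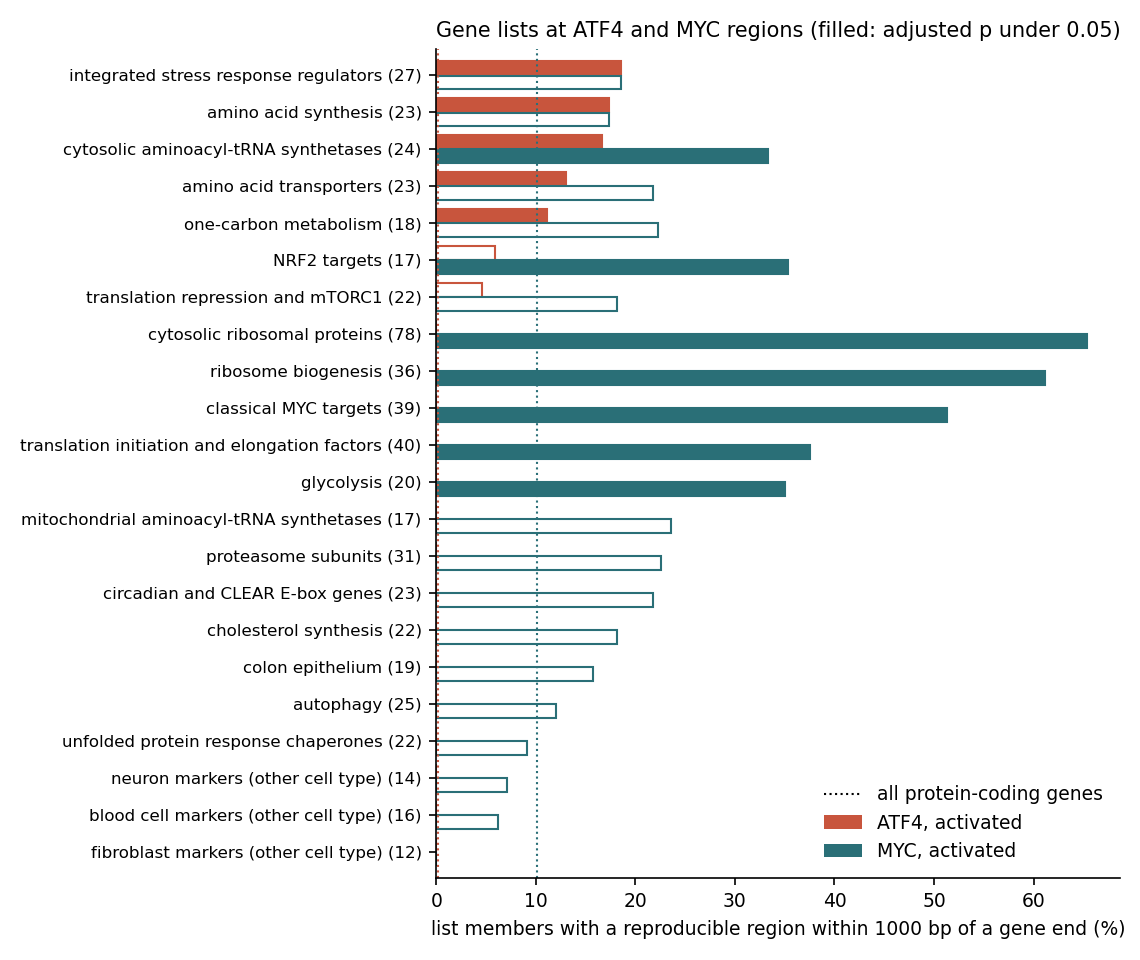
Percent of the members of each of the 22 gene lists (number of members in brackets) with a reproducible region within 1000 bp of a gene end, for ATF4 (red) and MYC (teal) in activated cells, filled where the adjusted p was under 0.05, with dotted lines at the share of all 19974 genes. ATF4 passed at 5 lists, led by stress response regulators (18.5%), and MYC at 7, led by cytosolic ribosomal proteins (65.4%).

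ATF4 regions lay at gene ends less often than MYC regions. ATF4 regions at gene ends were those of FGF21, CHAC1, PCK2 and IARS1. Those of ASNS, SLC7A5 and SLC43A1 lay inside the annotated gene span, 20788, 15766 and 9158 bp from its nearest end. The spans hold no transcription starts, so a region at a start within a span counts as inside the gene. The shares at gene ends are therefore not shares at promoters. In activated cells 34 of 352 ATF4 regions (9.66%, interval 6.78 to 13.2%) and 1756 of 6313 MYC regions (27.8%, 26.7 to 28.9%) were centred within 1000 bp of a gene end (odds ratio 0.28, two-sided Fisher's exact p = 3.10e-16). In control cells the ATF4 share was 13 of 151 (8.61%), not distinguishable from that in activated cells (odds ratio 1.13, Fisher's exact p = 0.867). Without ATF4 control replicate 2 this odds ratio was 1.67 (exact p = 0.0269), and without ATF4 activated replicate 1 or 2 it was 0.966 and 0.685. Inside genes lay 39.7% of control ATF4, 46.9% of activated ATF4 and 56.9% of MYC regions. By library, in replicates 1 and 2, 6.004% and 6.71% of control ATF4 peaks, 6.06% and 8.38% of activated ATF4 peaks and 24.4% and 27.7% of MYC peaks were centred at a gene end. Inside a gene lay 42.9% and 45.8% of control ATF4, 45.3% and 46.2% of activated ATF4 and 55.2% and 56.4% of MYC peaks.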

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

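Peaks of at least 4-fold over background, leaving out chromosomes 2 and 8, a common lowest tag count and regions inside genes were chosen only after the data were seen. Of 220 alternative values, 169 stayed within their limits, 43 moved, 4 newly passed a threshold and 4 reversed. In all alternatives run, the overlap of ATF4 with MYC regions exceeded random placement, genes with both factors were enriched and ATF4 regions lay at gene ends less often than MYC regions. The positive median ATF4 tag change held in 8 of 8 alternatives other than median centring. The 39 higher ATF4 regions became 0 with a replicate block, with median centring (9 lower), with a mean of at least 20 tags (7 regions tested) and without any 1 library (0 to 0 higher, 0 to 0 lower). The replicate numbers are not stated to pair samples, and there are only 2 such pairs. Over the 105 common regions, deviations of same-numbered libraries correlated at 0.0976. Depth and the share of peaks on chromosome 8 did follow the replicate number. So did the presence of peaks, with 68 and 56 regions only in the pairs of replicates 1 and 2, against 15 and 34 in the remaining pairing. The result with the block therefore cannot be set aside. In the fit with the replicate block 37 regions were higher at an unadjusted p under 0.05 and the smallest limma adjusted p was 0.115. Replicate overlap in the upper 50% of each list was 26.2% in ATF4 control, 42.5% in ATF4 activated and 86.4% in MYC. It was 22.9%, 34.4% and 76.3% without chromosomes 2 and 8, 34.9% in ATF4 activated at 4-fold and 33.0% from a common lowest tag count, and for MYC 59.6% with shortened lists, 66.2% with overlap of at least 50% and 74.2% by centres within 200 bp. Control ATF4 regions numbered 85 at 4-fold, and control-only regions 1 at 4-fold and 11 in the upper 50%. Leaving out libraries gave 151 to 1579 control, 352 to 2231 activated, 113 to 172 shared, 180 to 1952 activated-only and 25 to 1288 control-only regions, since the remaining library alone then defines its condition. Enriched lists within 5000 bp numbered 4 (ATF4 control), 8 (ATF4 activated) and 5 (both factors), within 200 bp 2 and 2 for ATF4 control and activated, and with regions inside genes 3 (ATF4 control) and 6 (both factors). Leaving out libraries gave 1 to 4 lists for ATF4 control, 5 to 5 for ATF4 activated, 7 to 11 for MYC and 3 to 5 for both. The odds ratio of the gene-end share, ATF4 activated against control, reversed to 0.853 within 200 bp and 0.828 at 4-fold and ranged from 0.685 to 1.67 with libraries left out, and that of MYC overlap, activated-only against shared, from 0.0889 to 0.672. The cause was not tested except where stated. Not run were the motif alternatives, for which no genome was used, and the DESeq2 alternative, since the replicate 2 lists hold no whole counts.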

Other observations

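The tests of sequencing depth, of extra chromosome 8 copies in replicate 1 cells, of peaks near the calling limit, of background tags at MYC peaks near the MYC gene and of reads from the MycER insert were chosen only after the results were seen. Strong ATF4 regions also lay beyond the window at gene ends. DDIT4, an inhibitor of mTORC1, had a region 1008 bp from its end (chromosome 10, 72272806 to 72273027) with 40.5 and 38.4 tags in activated replicates 1 and 2 and 26.8 and 20.9 in control (limma adjusted p = 0.0721). TRIB3, a stress-induced pseudokinase, had one at 4540 bp (log2 change 0.22, adjusted p = 0.512) and HSPA5, the chaperone BiP, one at 2131 bp (19.6 and 21.5 against 16.1 and 13.1 tags, adjusted p = 0.18). The region 5901 bp from EREG, an epidermal growth factor receptor ligand, rose from a mean of 11.22 to 19.85 tags (adjusted p = 0.0315). These genes were chosen after their values were seen.

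Further members of the synthetase and amino acid lists with an ATF4 region inside the gene, also chosen after their values were seen, were GARS1 (6.81 and 10.2 tags in activated replicates 1 and 2), EEF1E1 (4.81 and 5.02), ASS1, argininosuccinate synthase (8.42 and 7.64), and SLC3A2 (6.81 and 10.4). TXNRD1 of the NRF2 list, chosen in the same way, had 4.81 and 7.43. The strongest MYC regions lay away from gene ends, inside ELFN1 (36.1 and 53.1 tags in replicates 1 and 2) and CYTH1 (32.3 and 45.7), and 18060 bp from PKDCC (32.3 and 44.3), chosen in the same way. Common ATF4 regions on and off MYC regions had a median log2 change of 0.53 (26 regions, 9 higher) and 0.55 (30 of the others higher).

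ATF4 tags at the 105 common regions were higher after activation. A difference in depth is argued against by replicate 2, where the control and activated libraries held 50.3 and 49.75 M tags and the median log2 ratio was 0.74 (95% bootstrap interval 0.63 to 0.83), against 0.37 in replicate 1, where they held 22.4 and 24.95 M. A single factor for every region in each activated library, such as a more efficient immunoprecipitation, was simulated. The ratios of the 2 replicates were then nearly unrelated across regions (mean Spearman's rho 0.0174). In the data rho was 0.296 over 82 regions of at least 4-fold over background (one-sided permutation p = 0.0034), which 1.1% of simulations reached. It was 0.53 over 32 regions of at least 10-fold, for which no simulation was run. The simulations did not repeat the peak calling or the 4-fold filter that these regions had passed, so they cannot exclude a single factor. Regions are not independent replicates. Whether a single factor explains or adds to the change stays open. Centring on these same regions removes a technical factor and a general gain in binding alike. MYC activation itself stays open as a hypothesis with 2 libraries per condition, and an effect of the inducer itself cannot be told apart from it.

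Chromosome 8, with 4.79% of genome length, held 24.1% of peaks in replicate 1 against 7.92% in replicate 2 for ATF4 control, 19.3% against 6.90% for ATF4 activated and 8.73% against 4.24% for MYC, and chromosome 2 differed the same way by less (12.9% against 7.28%, 11.3% against 8.02% and 9.59% against 7.78%), for which no explanation was tested. Extra copies of chromosome 8 in the replicate 1 cells only are argued against by tags at MYC regions called in both replicates, where it exceeded the chromosomes other than 2 and 8 in replicate 1 over replicate 2 by a log2 ratio of only 0.0613 (interval 0.0185 to 0.121). More copies in all cells, the background library included, are a candidate explanation for part of it, as background tags at MYC replicate 2 peaks were 1.38 times as high on chromosome 8 (1.33 to 1.43). Peaks near the calling limit are another, as the share on chromosome 8 in the lower 50% of the ATF4 replicate 1 lists was 2.5 and 2.75 times that in the upper 50%, against 0.602 and 0.638 times in the ATF4 replicate 2 lists. Why the share is higher in the replicate 1 lists stays open, and since the design gives no group that parts the replicates, no biological explanation was tested.

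All 4 ATF4 lists and neither MYC list held a peak inside the MYC gene (chromosome 8, 127740476 to 127740789), with a fold over background of 2.39 and 1.55 in control and 1.95 and 1.83 in activated replicates 1 and 2. Extra copies of the surrounding segment would raise background tags at other peaks nearby, and in 0 of the 3 ATF4 lists with another peak within 1 Mb (16 peaks in all, none in ATF4 control replicate 2) were they as high. The 18 peaks of the MYC replicate 2 list there had at most 8 background tags, against 20 and 19 at this peak in the ATF4 replicate 2 lists, which argues against as many copies at those peaks. Sites with high background are less likely to be called as peaks, so extra copies between those peaks stay open. Reads of the MYC part of the MycER insert, mapped to the MYC gene, are a candidate explanation, as background tags at this peak were at least 3.38 times the median of the list in each of the 4 lists. The ATF4 lists may share 1 background library (about 43.3 M tags in both replicate 2 lists). Their background tags then do not count as separate observations. No biological explanation was tested, and ATF4 binding within the MYC gene stays open.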
